A study of Mus musculus with 8 samples.

How the data were processed

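ATAC-seq cuts accessible DNA with a transposase that carries sequencing adapters, so that open chromatin yields local excesses of reads called peaks. The data are 8 peak lists, 1 per library, from hippocampal microglia of mice aged 3 weeks, 4 from control (Ctrl) and 4 from FGR animals. Per the labels, DNA cutting and library preparation followed the Vazyme Hyperactive ATAC-Seq kit, and the mice were heterozygous for a Tmem119-tdTomato reporter. The submitters' processing notes name Trim Galore 0.6.5, Bowtie2 2.4.5, SAMtools 1.3.1, MACS2 2.2.7.1, DiffBind 3.12.0 and the genome build mm10, with no role, order or settings. Read shifting, duplicate removal and blacklist filtering are not given in the sources used here. Peaks were called separately for each library, since each has its own list.

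Each list gives a peak's position and summit together with values that are the authors' own for that peak. The deposited score is a whole number made for display and was not used in any test. The deposited fold is a ratio of the summit pileup to the local background. The deposited −log10 p and −log10 q values measure how far the pileup exceeds that background. Fold and −log10 q were used only to rank, describe or filter peaks within their own list. The smallest −log10 q in any list was 1.31, and no peak was shorter than 200 bp. Read totals per library were not used here. A depth measure was instead recovered from the authors' fold and −log10 p, which fit a Poisson tail with a whole-number pileup for 100% of peaks in every list within a tolerance of 0.001 on the −log10 scale. The lowest local background of a list was taken as the library's background coverage in extended reads per base. It was 4.53, 3.01, 4.04 and 6.05 in Ctrl replicates 1 to 4 and 3.82, 3.52, 4.82 and 4.60 in FGR replicates 1 to 4. As a check on simulated data, the pileup was recovered for 3000 of 3000 peaks.

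Gene positions came from a RefSeq gene table of assembly GRCm38.p6, which has the coordinates of mm10, for 21883 protein-coding genes on the autosomes, X and Y. The table gives neither strand nor exons, and no genome sequence was used here. The planned promoter measure was therefore replaced by a gene-end peak, a peak that overlaps the 1 kb on either side of either annotated end of a gene, and the nearest transcription start by the nearest gene end. Each gene thus contributes its 5′ and its 3′ end, and the measure is not one of promoters alone. The planned search for transcription factor motifs was not run. A locus is the gene span with 20 kb on each side.

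The lists of all libraries were merged into union regions wherever peaks shared at least 1 bp, and a region counted as called in a library when any of its peaks overlapped it. Single values per library were compared with an exact two-sided permutation test over the 70 assignments of 8 libraries to 4 and 4, whose smallest p is 0.0286. Similarity of peak sets was the Jaccard index, the bases shared by a pair over the bases covered by either, with a one-sided exact test over 35 splits. Regions were tested with Fisher's exact test, and 25 gene lists written before the data were examined were tested as the share of peaks in their loci and as the percent of members with a gene-end peak. Of 406 listed symbols, 405 matched the table. Peaks per locus were compared with limma 3.58.1 in R 4.3.3, with a trend, on log2 of peaks plus 0.5 per 10000 peaks of the library, over 8034 loci with a mean of at least 2 peaks. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

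Scripts were tested on simulated data. Of 200 FGR-only and 50 Ctrl-only regions placed among 20000, all 200 and all 50 were found. In simulated locus counts with 200 of 8034 loci changed between FGR and Ctrl, limma called 2 of the 200 at a fold of 2, which is 1%, and 83 at a fold of 4, which is 41.5%, with 0 and 1 false calls. Peak counts per locus are small, so that only large differences at a locus were detectable.

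Named genes followed a rule fixed before the data were examined. It takes 12 microglia genes, list members whose gene-end peak differs by 3 or 4 libraries between groups, up to 8 genes and 5 regions per direction called in 4 of 4 against 0 of 4 libraries ordered by the lowest within-list percentile of −log10 q, and up to 6 limma loci per direction. Some genes that the rule or a later choice would name are not reported here. Any other gene named was chosen after its values were seen, and the text says so.

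Replicates 1 and 2 carry older sample numbers than replicates 3 and 4, and these are called deposit sets 1 and 2. Whether the sets were sequenced or processed apart is not given in the sources used here. FGR libraries 1 and 3, and FGR libraries 2 and 4, shared more identical summits than other pairs. Ctrl libraries 1 and 3, and Ctrl libraries 2 and 4, did not, since Ctrl 1 and 2 have displaced summits, and were paired by summits exactly 200 bp apart and by regions called only in the pair. The mean of each of these pairs was therefore used as 1 value in every mean ± SD, with n = 2 pairs per group, while the tests planned on 8 libraries are given as planned and with the pairs averaged. With 2 against 2 values the smallest exact p is 0.333. Alternatives fixed beforehand were a stricter peak threshold of −log10 q of at least 5, lists of equal length (the 10862 strongest peaks of each library), leaving out each library, blocks by replicate number and by deposit set, autosomes only, and other windows, overlaps, filters and pseudocounts. Settings added after seeing the data left out Ctrl replicates 1 and 2 together, averaged the pairs or entered them as a correlated block, used deposit set 2 alone, or divided peak numbers by background coverage.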

Results

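Accessible chromatin was mapped by ATAC-seq in microglia, the resident macrophages of the brain, from the hippocampus of mice aged 3 weeks. There were 4 libraries from control animals and 4 from FGR animals, the label given to offspring whose growth was restricted in the womb. The comparison asks whether growth restriction before birth leaves a difference in microglial chromatin. The labels do not say how many animals stand behind a library, their sex, or whether libraries came from separate animals. Each library was represented by its own list of peaks, with 16111, 10862, 22705 and 24195 peaks in Ctrl replicates 1 to 4 and 27209, 23327, 29501 and 26246 in FGR replicates 1 to 4. P-values therefore measure differences against the spread between these libraries, whatever its source.

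The 8 libraries did not behave as 8 independent samples. FGR replicates 1 and 3 placed 9.14% of the summits of their shared regions at the identical base, and FGR replicates 2 and 4 placed 7.57% there. In the other 13 pairs among the 6 libraries FGR 1 to 4 and Ctrl 3 and 4, the share was between 1.76% and 2.14%. A further 1974 regions were called only in FGR replicates 1 and 3, and 946 only in FGR replicates 2 and 4, against 119 to 368 for the other pairs of FGR libraries. Ctrl replicates 1 and 2 stood apart from all others in peak shape, with median widths of 566 and 522 bp against 353 to 386 bp. Their summits lay a median of 138 to 140 bp from those of the other 6 libraries, which lay 36 to 44 bp from each other outside the FGR pairs just named. Between Ctrl 1 or 2 and the other 6, 0.371% to 1.16% of summits were exactly 200 bp apart, with the highest shares in Ctrl 1 with Ctrl 3 (1.16%) and Ctrl 2 with Ctrl 4 (0.940%). Replicates 1 and 3, and replicates 2 and 4, of a group were therefore counted as 1 sample each, so that means are over n = 2 pairs, although the Ctrl pairs shared at most 0.0396% of identical summits.

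**Figure D1:**
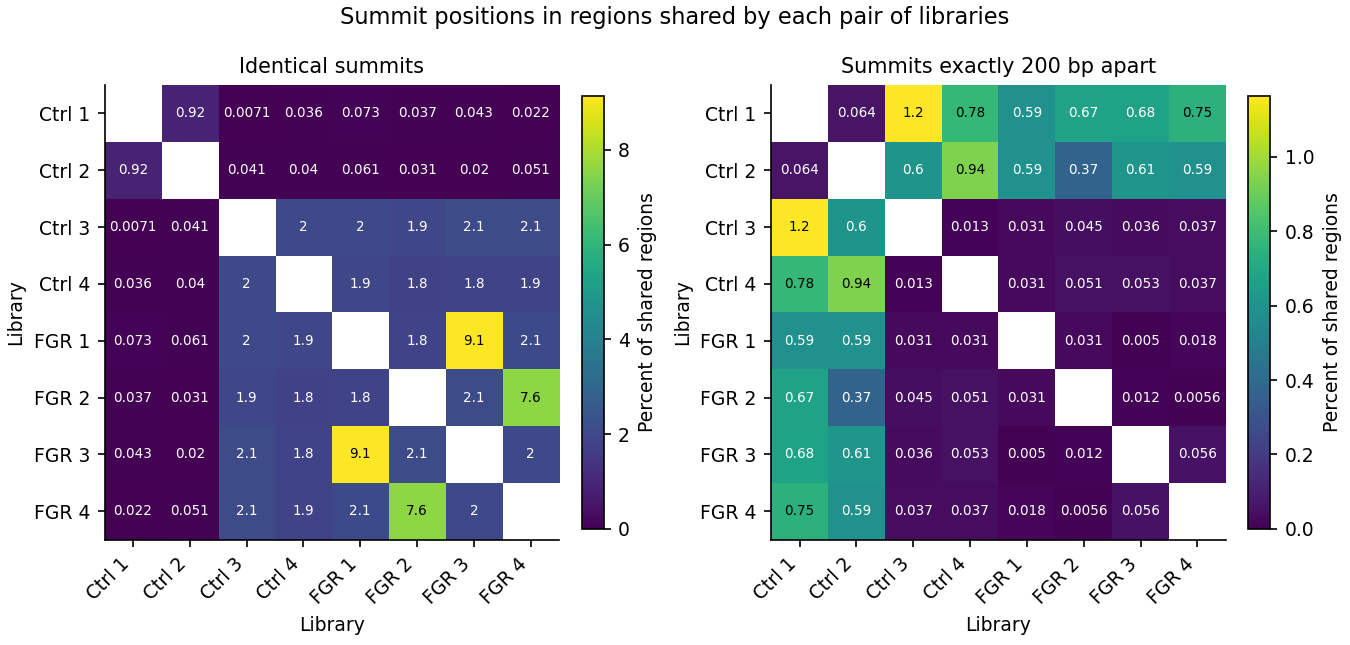
Percent of the regions shared by each pair of libraries whose strongest summits lie at the identical base (left) or exactly 200 bp apart (right), with libraries on both axes. FGR 1 with FGR 3 (9.14%) and FGR 2 with FGR 4 (7.57%) stand above the other pairs on the left, and Ctrl 1 and Ctrl 2 against the other 6 on the right.

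Tmem119, a microglial surface marker (chromosome 5, 113793729 to 113800396), had a gene-end peak in 8 of 8 libraries, at a median percentile of 82.8 of its list by −log10 q. Gene-end peaks were also called in all 8 libraries at the fractalkine receptor gene Cx3cr1, at Sall1, a transcription factor of microglial identity, and at Irf8, an interferon regulatory factor needed by microglia. Spi1, which encodes the myeloid factor PU.1, and the lipid receptor gene Trem2 each had one in 3 Ctrl and 4 FGR libraries, and the growth factor receptor gene Csf1r in 2 Ctrl and 4 FGR. Apoe, an apolipoprotein gene, had a gene-end peak in 2 libraries of each group, the antigen presentation gene Cd74 in 1 Ctrl library, the purinergic receptor gene P2ry12 in 1 FGR library and the lectin receptor gene Clec7a in none. The P2ry12 locus nevertheless held 3, 2, 5 and 6 peaks in Ctrl replicates 1 to 4 and 7 in each FGR library. The means were 4 ± 0 in Ctrl and 7 ± 0 in FGR (SD, n = 2 pairs). The Ctrl SD of 0 arises because each pair averages a library of each deposit set. These counts are not divided by list length, and FGR lists were longer on average. The P2ry12 locus did not pass the limma threshold.

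A gene-end peak was called in all 8 libraries for 6972 of 21883 protein-coding genes, or 31.9%. Among the fixed lists, the share was higher for immediate early genes, which respond quickly to stimulation (18 of 21 members), lysosome and phagocytosis (17 of 25), proliferation (14 of 21), hypoxia and glycolysis (15 of 25), oxidative phosphorylation (12 of 20) and insulin and growth factor signalling (13 of 21). It was lower for markers of neurons (0 of 19), monocytes and neutrophils (0 of 14) and lymphocytes (0 of 12). For these 9 lists Fisher's exact test gave adjusted p between 1.28e-05 and 0.0376. The other 16 lists did not pass. They were homeostatic microglia (7 of 23), microglia transcription factors (9 of 17), disease-associated microglia (5 of 23), interferon response (3 of 22), inflammatory response (14 of 26), MHC class I (6 of 9) and class II (1 of 7), complement and synapse engulfment (8 of 17), glucocorticoid response (5 of 14), lipid and cholesterol (7 of 19), TGF-beta signalling (8 of 13), and markers of astrocytes (1 of 13), oligodendrocyte lineage (1 of 14), endothelial and mural cells (1 of 12), border macrophages (0 of 8) and erythroid cells (0 of 7). A count over all 8 libraries is limited by the shortest list, that of Ctrl replicate 2, with a gene-end peak at 34.8% of all genes. In Ctrl 3 and 4 and in FGR, means of 67.4% and 71.7% of homeostatic microglia members had one. Of all protein-coding genes, 44.7% to 48.4% had one in these libraries, a comparison that was not tested. Genes active in many cell types tend to have open promoters in all of them, and the libraries hold no other cell type for comparison.

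**Figure D2:**
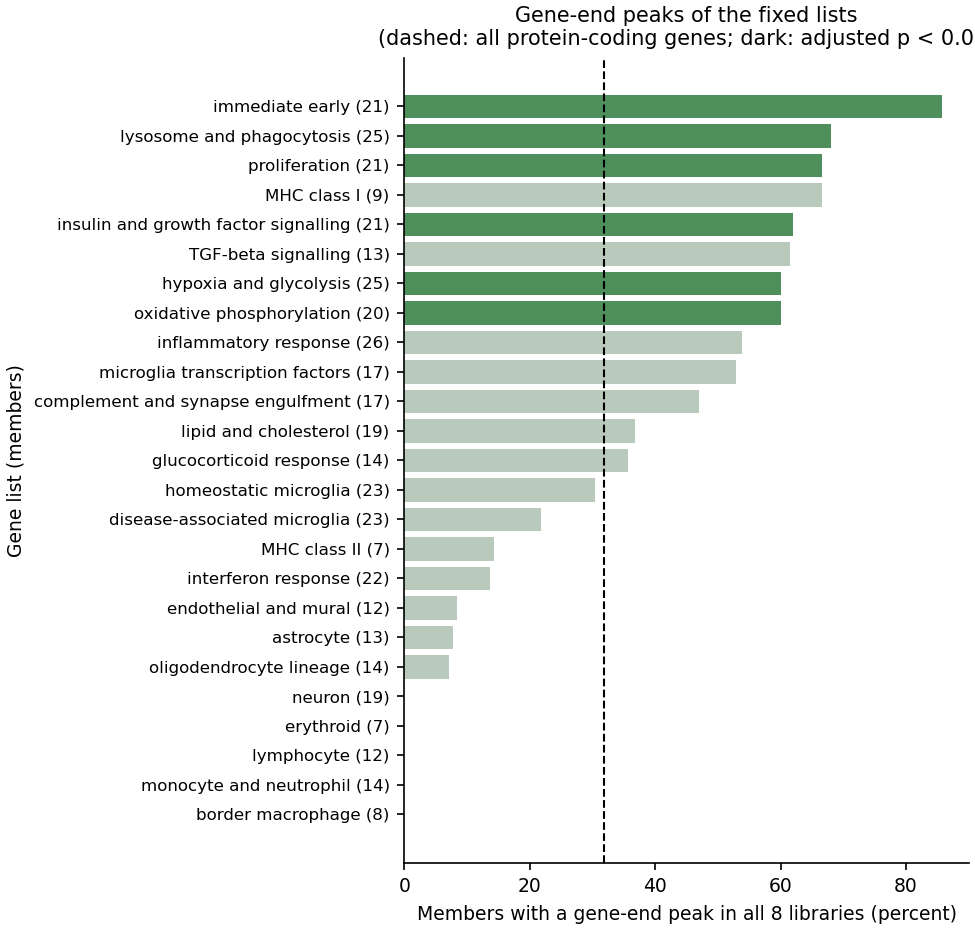
Percent of the members of each of 25 gene lists (vertical axis, number of members in brackets) with a gene-end peak in all 8 libraries. Dark bars passed Fisher's exact test against all protein-coding genes after adjustment, and the dashed line marks the 31.9% of all protein-coding genes.

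More peaks were called in FGR than in Ctrl libraries, and most of the additional peaks lay away from gene ends. The FGR libraries had 26571 ± 2523 peaks and the Ctrl libraries 18468 ± 1329 (SD, n = 2 pairs), a 1.44-fold difference, while single Ctrl libraries ranged from 10862 to 24195. Peaks away from gene ends numbered 16422 ± 2161 in FGR and 9569 ± 926 in Ctrl, and peaks at gene ends 10149 ± 363 and 8899 ± 403. Gene ends accordingly held 38.4% ± 2.31 of FGR peaks and 50.5% ± 3.42 of Ctrl peaks, with single Ctrl libraries from 43.0% to 62.8% and a mean of 43.3% in Ctrl 3 and 4. Each pair of either group averages a library of set 1 with one of set 2. A pair SD, here and in other paragraphs, can therefore lie well below the spread between libraries. In deposit set 2 alone, FGR libraries averaged 27873.5 and Ctrl libraries 23450 peaks, with 10352.5 and 10151.5 peaks at gene ends and 17521 and 13298.5 away from them. In deposit set 1 the means were 25268 and 13486.5 peaks, with 9945.5 and 7647 at gene ends and 15322.5 and 5839.5 away from them. Peaks covered 11.6 ± 1.32 Mb in FGR and 9.17 ± 0.772 Mb in Ctrl.

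The difference in peak number did not pass the exact permutation test over 8 libraries (p = 0.0571), and neither did covered length (exact p = 0.143). The gene-end share differed by -12.1 percentage points at the smallest p the design allows (exact p = 0.0286), and by -6.27 with lists of equal length (exact p = 0.0286). It no longer passed when any 1 FGR library was left out (exact p from 0.0857 to 0.114). Every FGR library still lay below every Ctrl library (35.9% to 41.4% against 43.0% to 62.8%), so the real assignment stayed the most negative. The p rose because, with unequal groups, assignments of the opposite sign gave differences at least as large. Background coverage, the depth measure, was 4.19 ± 0.187 in FGR and 4.41 ± 0.177 in Ctrl (exact p = 0.8). Single libraries ranged from 3.52 to 4.82 in FGR and from 3.01 to 6.05 in Ctrl. On average the FGR libraries were thus not the deeper ones on this measure. Per unit of background coverage, FGR libraries had 6391 ± 318 and Ctrl libraries 4197 ± 559 peaks (exact p = 0.0286). That ratio assumes that peak number rises in proportion to coverage. Ctrl 3 and Ctrl 4 did not show this, with 22705 peaks at 4.04 and 24195 at 6.05. Without Ctrl replicates 1 and 2 the difference in peak number was 3120.75 (exact p = 0.267) and that in gene-end share -4.94 percentage points (exact p = 0.0667, the smallest that 15 assignments allow). With the pairs averaged, no exact p can fall below 0.333, and the gene-end share reached that value.

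**Figure D3:**
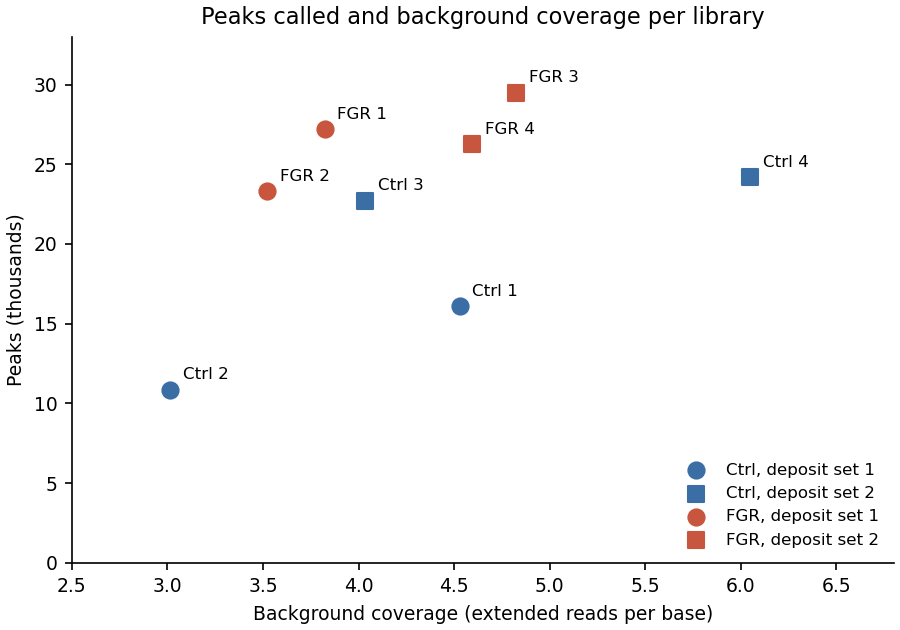
Number of peaks (vertical axis) against background coverage (extended reads per base) for each library, coloured by group, with circles for deposit set 1 and squares for deposit set 2. Ctrl 1 and Ctrl 2 lie lowest, with 16111 and 10862 peaks, while Ctrl 4 has the highest coverage, 6.05.

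**Figure D4:**
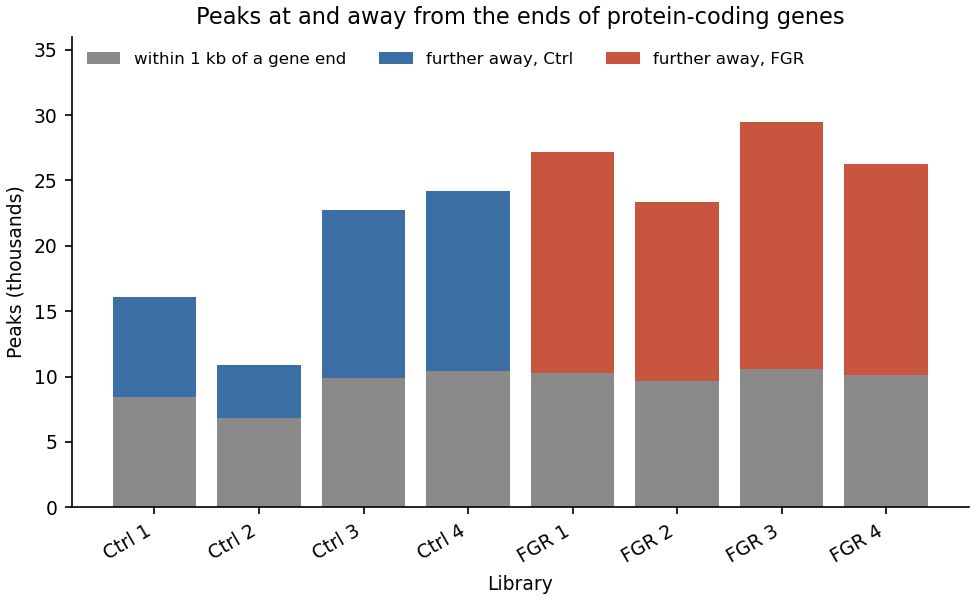
Number of peaks within 1 kb of an end of a protein-coding gene (grey) and further away (blue for Ctrl, red for FGR) in each library. Peaks at gene ends number 9658 to 10578 in the FGR libraries and 9899 and 10404 in Ctrl 3 and 4, while peaks further away number 13669 to 18923 and 12806 and 13791.

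Among 52251 union regions, 454 were called in all 4 FGR and no Ctrl libraries, and 14 in all 4 Ctrl and no FGR libraries. Of the 454, 403 lay over 1 kb from a gene end and 272 inside the span of a protein-coding gene. The strongest by rank were an intergenic region on chromosome 16 (55663938 to 55664267), whose nearest gene end, 147108 bp away, was that of the NF-κB regulator gene Nfkbiz, and a region on chromosome 11 (71817232 to 71817887), 27583 bp from Wscd1. They were followed by regions inside Chn2, a Rac GTPase-activating protein gene, on chromosome 6 (54119930 to 54120258), on chromosome 10 (83946536 to 83947046), 183774 bp from 1500009L16Rik, and inside Gas7 on chromosome 11 (67579114 to 67579666). Of the 454, 259 overlapped none of the 10862 strongest peaks of any FGR library. Only 3 of the 14 Ctrl regions lay away from gene ends, inside the phosphatase gene Dusp7 (chromosome 9, 106370567 to 106371251), the ectonucleotidase gene Entpd1 (chromosome 19, 40737008 to 40737476) and Arhgap9 (chromosome 10, 127323431 to 127323982). Entpd1 also holds 1 of the 454 FGR regions, at 40693029 to 40693763.

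No single region passed after adjustment by Fisher's exact test, whose smallest p of 0.0286 was reached by 468 of 43395 regions. At that smallest p, none could pass unless most of the 43395 regions reached it, so this outcome does not test single regions. When only the 10862 strongest peaks of each library were compared, 128 FGR and 90 Ctrl regions were separated between the groups, and only 10 of the original 454 were among the 128. Leaving out 1 library gave between 461 and 884 FGR regions and between 15 and 79 Ctrl regions. Fewer libraries loosen the requirement, so neither count could fall and the ranges do not test for a loss. Without Ctrl replicates 1 and 2, where a Ctrl region needs only 2 libraries, the counts were 531 for FGR and 385 for Ctrl. In deposit set 2 alone, 1601 regions were called in both FGR and neither Ctrl library, and 635 the other way.

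At gene ends, 37 genes had a peak in all FGR and no Ctrl libraries and 5 the reverse. The strongest FGR genes were Zbtb7a, a zinc finger repressor gene, Zfp54, Pqlc3, Nccrp1, Krtcap2 and Fcgr2b, which encodes the inhibitory low-affinity IgG receptor, followed by the neighbours Cul9 and Srf, which share a peak. Their lowest percentile in an FGR list ran from 62.1 for Zbtb7a to 27.4 for Cul9 and Srf. The 5 Ctrl genes were the helicase gene Recql4, Slc25a53, Reep4, Fhl3 and Ltbp1, which encodes a latent TGF-beta binding protein. Equal-length lists turned the balance round, with 9 FGR and 71 Ctrl genes. Without Ctrl replicates 1 and 2 the counts were 48 and 70, but a Ctrl gene then needs only 2 libraries against 4 for an FGR gene, which by itself raises the Ctrl count.

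Of the 405 listed genes, 6 differed by 3 or more libraries. Ltbp1, of the TGF-beta list, had a gene-end peak in 4 Ctrl and 0 FGR libraries. The vascular growth factor receptor gene Flt1, an endothelial marker, had one in 1 Ctrl and 4 FGR libraries. The integrin gene Itgam, the MHC class II gene H2-Eb1, the interferon-induced gene Rsad2 and Tyms, which serves DNA synthesis, each had one in 0 Ctrl and 3 FGR libraries. With −log10 q of at least 5, the difference fell from 0.75 to 0.25 of libraries for Flt1, Itgam, H2-Eb1 and Rsad2. It went from -1 to -0.25 for Ltbp1 and stayed 0.75 for Tyms. With equal-length lists it was 0 for Flt1, Itgam, H2-Eb1, Rsad2 and Tyms, and -0.25 for Ltbp1. None of the 25 lists differed between the groups in the percent of members with a gene-end peak, the closest being complement and synapse engulfment with 57.4% ± 2.08 in Ctrl and 70.6% ± 0 in FGR (SD, n = 2 pairs, exact p = 0.0571, adjusted p = 1). The homeostatic microglia list had 54.3% ± 6.15 in Ctrl and 71.7% ± 0 in FGR (exact p = 0.171), but 67.4% in Ctrl replicates 3 and 4. Over single libraries the SDs were larger. In Ctrl and FGR they were 7.40 and 4.80 for complement and synapse engulfment, and 17.6 and 7.53 for homeostatic microglia.

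In the share of peaks, loci of oxidative phosphorylation genes held 22.4 ± 1.38 of every 10000 Ctrl peaks and 18.2 ± 0.784 of every 10000 FGR peaks. Loci of lipid and cholesterol genes held 25.7 ± 0.888 and 21.7 ± 1.31 (SD, n = 2 pairs). Both differences had an exact p of 0.0286 over 8 libraries, or 0.357 after adjustment over 25 lists, where 15 lists would have had to reach the smallest p to pass. Counted without division by list length, the same loci held 7.5 and 10.25 more peaks per FGR library (exact p = 0.343 for both), so the direction depends on the scaling. Without Ctrl replicates 1 and 2 both shares remained lower in FGR (exact p = 0.0667 for both). Homeostatic microglia loci held a mean of 30.7 per 10000 Ctrl peaks and 34.5 per 10000 FGR peaks, a difference of 3.77 (exact p = 0.114). That difference was 2.05 without Ctrl replicates 1 and 2 (exact p = 0.333). With equal-length lists it was 9.90 (exact p = 0.0286, not adjusted over the lists). The differences of oxidative phosphorylation and of lipid and cholesterol were then -1.15 (exact p = 0.571) and -0.460 (exact p = 0.914). The remaining 22 lists, including the markers of other brain and blood cells, had exact p from 0.0857 to 0.686. No list was enriched among the 454 FGR regions relative to other regions called in 4 libraries (Fisher's exact test, smallest adjusted p = 0.193).

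A single locus passed the limma test, that of Elmo1, whose product helps activate Rac during engulfment and cell movement. Elmo1 spans chromosome 13 from 20090507 to 20608353, and its locus held 4, 1, 8 and 9 peaks in Ctrl replicates 1 to 4 and 16, 13, 18 and 18 in FGR replicates 1 to 4. That is 2.66 ± 0.483 and 6.10 ± 0.159 per 10000 peaks (SD, n = 2 pairs), a log2 difference of 1.19 ± 0.22 (SE, limma adjusted p = 0.0232). Elmo1 holds 2 regions called in all FGR and no Ctrl libraries, at 20127638 to 20127926 and 20207101 to 20207481. Their peaks are among those counted above and are not separate support. No other locus passed, although 209 were higher and 1256 lower in FGR at an unadjusted p under 0.05 in limma. These are shares of all peaks of a library, which fall at a locus when peaks are gained elsewhere.

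The Elmo1 difference stayed positive in all 19 other settings, between 0.71 and 1.37 on the log2 scale. It lost significance in 7 of them. These included −log10 q of at least 5 (limma adjusted p = 0.0899, with 1 other locus called) and equal-length lists (limma adjusted p = 0.0595). The others were without Ctrl replicates 1 and 2 (0.71 ± 0.14 SE, limma adjusted p = 0.424), and without Ctrl replicate 1 or FGR replicate 2, 3 or 4 (limma adjusted p = 0.0615 to 0.155). With the pairs averaged it was 0.96 ± 0.19 (SE, limma adjusted p = 0.0131), as 1 of 20 loci called. With a pseudocount of 1 limma called 7 higher and 50 lower loci. With equal-length lists it called 13 higher and 7 lower, Elmo1 not among them. Among the 234 listed loci tested, none passed over all loci. Adjusted over the list alone, Myrf, a myelin regulator gene of the oligodendrocyte list, was lower in FGR (log2 -1.16 ± 0.25 SE, limma adjusted p = 0.000111 over 3 loci), and Flt1 of the endothelial list was higher (0.96 ± 0.28 SE, limma adjusted p = 0.00466 over 3 loci). Neither p was adjusted over the 25 lists as well.

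**Figure D5:**
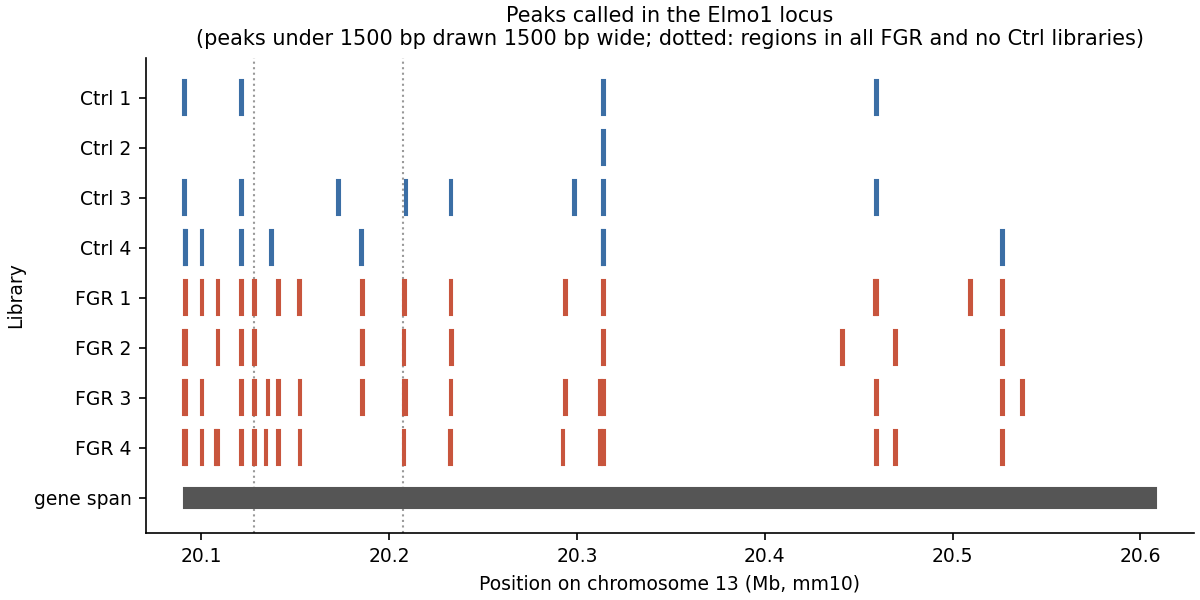
Peaks called along the Elmo1 locus on chromosome 13 (Mb, horizontal axis) in each library (rows, Ctrl blue and FGR red), with the gene span in grey and dotted lines at the 2 regions called in all FGR and no Ctrl libraries. The FGR rows hold 13 to 18 peaks and the Ctrl rows 1 to 9.

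Libraries of a group resembled each other more than libraries of different groups. The mean Jaccard index was 0.468 within Ctrl, 0.498 within FGR and 0.442 between groups, an excess of 0.0406 that was the largest of the 35 splits (one-sided exact p = 0.0286). That p treats the 8 libraries as independent. Only 3 of the splits keep the resembling pairs together, too few for a p under 0.05. The FGR mean includes FGR 1 with FGR 3 (0.559) and FGR 2 with FGR 4 (0.569). The 4 other FGR pairs averaged 0.465, below the 0.474 of the 8 pairs of Ctrl 3 or 4 with an FGR library. Without Ctrl replicates 1 and 2 the excess was 0.0244 (one-sided exact p = 0.2).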

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

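In 113 groups of 4 libraries, 11 values lay far from the other 3 by the ratio of the gap to the range. For continuous, normally distributed values chance alone gives about 1 in 20, which would be 5.65 of 113. That rate does not hold for percentages of few members, where a tie of 3 libraries puts the ratio at its highest value. All 11 are list values, and 10 of them are percentages of few list members, in which 3 libraries tie and 1 differs by 1 to 3 genes. No explanation was tested for them.

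Loci of disease-associated microglia genes held 24.4 of every 10000 peaks in Ctrl replicate 4, against 28.5 to 29.2 in the other Ctrl libraries. For microglia transcription factors, 58.8% of members had a gene-end peak in Ctrl replicate 2 and 64.7% in FGR replicate 2, against 70.6% in the others of each group. For MHC class II the value was 57.1% in FGR replicate 1 against 71.4%. Insulin and growth factor signalling reached 81.0% in Ctrl replicate 4 against 66.7%, and immediate early genes 90.5% there against 85.7%. FGR replicate 4 had 76.9% for TGF-beta signalling against 84.6%, 23.1% for astrocyte markers against 7.69% and 25% for border macrophage markers against 12.5%. Border macrophage markers were at 0% in Ctrl replicate 2 against 12.5%, and endothelial and mural markers at 25% in FGR replicate 1 against 16.7%.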

How the results depend on the processing

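Settings without Ctrl replicates 1 and 2 together, with pairs averaged or correlated, with deposit set 2 alone and per background coverage were chosen after seeing the data. The motif settings were not run, since no genome sequence was used, and motif shares have no value. The cause of each change below was not tested, except where fewer assignments or libraries make it.

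Leaving out 1 library at a time moved the FGR minus Ctrl difference in peak number between 5567 and 10011, past the threshold only without Ctrl replicate 4, and that in gene-end share between -14.6 and -8.03, not past it without any 1 FGR library. Every FGR gene-end share still lay below every Ctrl share, so assignments of the opposite sign made that loss. The excess of similarity ran from 0.0312 to 0.0573 and also lost significance without each FGR library. FGR regions numbered 461 to 884, Ctrl regions 15 to 79, FGR genes 38 to 109, Ctrl genes 5 to 20, lists by locus share at an unadjusted p under 0.05 1 to 4, lists by gene ends 0 to 1, and limma loci 0 to 15. Counts of regions and genes can only stay or rise when a library is left out. Ctrl regions and genes moved most without Ctrl replicate 2 (79 and 20), FGR regions and genes without Ctrl replicate 4 (884 and 109).

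With −log10 q of at least 5 there were 8 Ctrl regions, 2 Ctrl genes and 1 list by locus share, homeostatic microglia (5.26, exact p = 0.0286), while oxidative phosphorylation (-2.58, exact p = 0.143) and lipid and cholesterol (-3.73, exact p = 0.0857) no longer passed. Equal-length lists turned covered length to -0.167 Mb and gave 128 FGR and 90 Ctrl regions, 9 and 71 genes, 1 list by locus share, 2 lists by gene ends and 20 limma loci. Requiring 3 of 4 against 0 of 4 libraries gave 1400 and 94 regions, and requiring a peak over at least 0.5 of a region gave 27 Ctrl regions. The 5 kb flank gave 1 list and 3 limma loci, raw peak numbers 6 lists (with oxidative phosphorylation at 7.5 and lipid and cholesterol at 10.25 more peaks in FGR), subtraction of all genes 1 list by gene ends, loci with a mean of at least 1 peak 3 limma loci, and a pseudocount of 1 57. Within 2.5 kb of gene ends the Cd74 difference turned to 0.25 of libraries.

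Same-numbered Ctrl and FGR libraries did not deviate together (correlations from -0.0434 to 0.0169 over 16043 regions). Differently numbered libraries gave -0.0681 to 0.0588. These calls thus show no pairing of the samples by number, but do not exclude one. With the replicate block the gene-end share difference stayed -12.1 (exact p = 0.125, the smallest of 16 assignments), 0 lists could pass and limma called 141 loci (54 higher, 87 lower). With the deposit set block the share stayed -12.1 (exact p = 0.0556, the smallest of 36) and 0 lists could pass. Without both Ctrl libraries 1 and 2 the share difference was -4.94, the similarity excess 0.0244, Ctrl regions 385, Ctrl genes 70, lists 0 and limma loci 0. With pairs averaged the share stayed -12.1, lists 0 by construction and limma loci 20, or 41 (13 higher, 28 lower) with pairs as a correlated block. Deposit set 2 alone gave -6.08 for the share and 1601 and 635 regions, and peaks per unit of background coverage differed by 2194. For the main results, 96 combinations of result and setting stayed, 59 counts moved, 14 lost significance, 2 gained it and 1 changed sign. For named lists, genes, regions and the called locus, 517 stayed, 40 moved, 23 lost significance, 4 gained it and 3 changed sign.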

Other observations

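The genes and tests in this part were chosen after the result was seen, except the planned limma test with its splits, and Arhgap9, Chn2 and Elmo1, which the fixed rule names. The spans of 13 genes each hold 2 of the 454 regions called in all FGR and no Ctrl libraries, and no span holds 3. They include Bicral, Cdh23, Chn2, Cux1, Elmo1, Epb41, Lims1, Lyn, Maml2, Prkca, Sgk1 and Wbp1l. Among them, Lyn encodes a Src-family kinase of myeloid receptors (chromosome 4, 3678068 to 3791612), Prkca a protein kinase C (chromosome 11, 107933387 to 108343888), and Sgk1 a kinase induced by glucocorticoids (chromosome 10, 21882184 to 21999903). The 13 genes have a median length of 152 kb, against 17.2 kb for all protein-coding genes, and longer genes offer more room for such regions.

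Just short of the limma threshold, the locus of Arhgap9 had a log2 difference of -1.48 ± 0.30 (SE, limma adjusted p = 0.0602) and holds 1 of the Ctrl regions. It was followed by Myrf (-1.16 ± 0.25, limma adjusted p = 0.0991), Utp11 (-1.13 ± 0.26), Gli1 (-1.15 ± 0.26) and, in the other direction, Nid2 (0.97 ± 0.23), the last 3 with a limma adjusted p of 0.117. The Y-linked helicase gene Ddx3y had a gene-end peak in 3 Ctrl and 4 FGR libraries and Eif2s3y in 1 of each, while Uty and Kdm5d had none.

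For the resemblance of replicates 1 and 3, and of 2 and 4, a batch of deposition is argued against. In regions called in all 8 libraries, pairs within 1 deposit set shared at most 2.70% of summits, while the FGR pairs across sets shared 9.43% and 7.95%. A candidate explanation is that both deposits hold the same material or reads in part, since 7.95%, the lower of these values, is over the 1.99% to 2.70% of the other pairs of like calling. For Ctrl 1 with 3 and Ctrl 2 with 4, the shares of summits 200 bp apart were 1.16% and 0.940%, against at most 0.777% for other pairs with Ctrl 1 or 2, and regions called in that pair only numbered 164 and 60, against 18 to 50 for Ctrl 1 and 4 to 12 for Ctrl 2 with the rest of the other 6 libraries. Whether the deposits are resequenced libraries or sister libraries of 1 animal or pool stays open.

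For the wider peaks and displaced summits of Ctrl replicates 1 and 2, low depth is argued against for Ctrl 1. Its background coverage was 4.53, above that of 3 of the other 6 libraries. It still had at least 70.6% of its summits over 100 bp from those of each of the other 6. Ctrl 2 had the lowest coverage of all 8 libraries, 3.01, so low depth stays open for it. Reads placed differently before peaks were called may account for the pattern in both libraries. Summits exactly 200 bp apart made up at least 0.371% in all 12 pairs of Ctrl 1 or 2 with the other 6, against at most 0.0559% among those 6. No biological explanation was tested.

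For the larger number of peaks and regions in FGR, deeper FGR libraries are argued against, since background coverage averaged 4.19 in FGR, 4.41 in Ctrl and 5.04 in Ctrl 3 and 4. Peaks per unit of coverage still differed (exact p = 0.0286, or 0.0667 without Ctrl 1 and 2 and 0.333 with pairs averaged, each the smallest possible). That ratio cannot decide the question, because peak number did not rise in proportion to coverage. Ctrl 3 had 22705 peaks at 4.04 and Ctrl 4 had 24195 at 6.05. The differing calls of Ctrl 1 and 2 may account for at least part of the larger number in FGR. Leaving out both took the ratio of FGR to Ctrl regions to 1.38, against 3.90 to 88.6 for the 5 other ways to leave out a pair of Ctrl libraries. The lower ratio comes from 385 Ctrl regions, which then need only 2 libraries. FGR regions numbered 531. That count cannot fall below 454 when Ctrl libraries are left out, so it sets no limit on this explanation. Only the real split, 1 of 35, reached 454 regions, with 178 the highest other, which sets it apart from chance groupings if the libraries are independent. Only 3 splits keep the resembling pairs together, too few for a share under 0.05, and within deposit set 2, with 2 libraries on each side, the ratio of 2.52 compares with 1.07 and 1.58 in its other splits. Growth restriction and library quality both stay open as sources of what remains.

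Chance cannot be excluded for the other counts. For the 14 Ctrl regions, 2 of the 35 splits gave as many in their smaller side, with 34 the highest other. For the 37 FGR genes, 2 of 35 did, and the split that sets Ctrl 1, Ctrl 2, FGR 2 and FGR 4 against the rest gave 40. For the 5 Ctrl genes, 2 of 35 did, with 7 the highest other. For the single limma locus, 2 of 35 splits called as many, with 1 the highest other.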
